A study of Homo sapiens with 4 samples.

How the data were processed

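Gene expression was measured on 4 Affymetrix Human Gene ST arrays, each hybridised with RNA from MDA-MB-231, an established human breast cancer cell line of the triple-negative, mesenchymal-like type. Per the labels, 2 arrays came from cells expressing a non-specific short hairpin RNA (shNS) and 2 from cells expressing a hairpin against DBC1 (shDBC1), whose current gene symbol is CCAR2. The series design describes the replicates of each line as independent and biological. The cells received no treatment, and total RNA was purified on columns, converted to cDNA and labelled with biotin, per the labels' protocols.

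The deposited values are normalised log2 intensities, 1 per probe set and array. The authors used GCOS and RMA (robust multi-array average, which corrects background, normalises between arrays and summarises the probes of a probe set), per the submitters' processing notes. Their versions, any filters and the genome build of the probe annotation are not given in the sources used here, so no coordinates are printed. The log2 scale was inferred from the values, which ran from 2.52 to 14.1, and from RMA being named. Array medians were 7.40 and 7.32 in shNS and 7.39 and 7.37 in shDBC1 on that scale. RMA compresses folds of dim genes, and normalisation between arrays would hide a shift shared by all genes. For arrays the number of arrays, 2 per group, limits the precision.

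Of 33297 probe sets, 19460 carried 1 gene symbol in the platform's annotation table, 1754 carried several and 12083 were unnamed in it. The single symbols were looked up by gene identifier in a table of RefSeq genes, which matched 19429 and changed 0 of them. Probe sets with several symbols were not used to name a gene. Each of the 18417 genes was represented by its brightest probe set over the 4 arrays, a choice that mattered for the 769 genes with more than 1. Genes whose mean lay below the 25th percentile of all genes, a log2 value of 6.58, were left out (4604 genes), and 13813 were tested. BRINP1, an unrelated gene that has also been called DBC1, was not taken for the target. Histone genes, the AKR1C genes and the CXCL1 group have close sequence copies, so values of single members are uncertain.

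The comparison of shDBC1 with shNS was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, two-sided), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The fit had 2 residual and 2.60 prior degrees of freedom. Errors of log2 fold changes are the standard errors (SE) of that fit, intervals are at 95%, and group levels are means with the standard deviation (SD) of 2 arrays. Gene lists were tested with limma's camera, which asks whether a list's members are shifted relative to the other genes, at a preset inter-gene correlation of 0.01, adjusted over the 22 lists. Camera with an estimated correlation and the fry rotation test were run beside it. With an estimated correlation camera takes its test on the residual degrees of freedom, 2 in this fit, so few lists could pass. A call lost there does not by itself show that correlation among the members made it. The estimated correlation is therefore given beside the lists called. Adjustment over a list's own members is given as adjusted over the list alone. It was not corrected for the number of lists, and 3 of the 22 lists had a member that passed it.

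The groups, the test, the lists, the alternatives and the rule for named genes were set before the data were examined. The rule took CCAR2, then 12 genes higher and 12 lower whose shDBC1 arrays both lay on the same side of both shNS arrays. These were to be ranked by fold among genes past the threshold and otherwise filled by the smallest unadjusted p, leaving out small RNAs and unnamed reading frames. It added up to 4 members of each list by the smallest p, the PEA3 factors ETV1, ETV4 and ETV5, and SIRT1. Any other gene is named as chosen after its values were seen. A further 6 lists of markers of other cell types were set for counts only.

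The procedure was tested on simulated data for this comparison, with 13813 genes, 2 arrays per group, 200 changed genes and 20 runs. It recovered 23.9% of genes changed 2-fold and 86.6% of those changed 4-fold, with a mean of 7.15 false calls. A list of 30 genes shifted by -0.2 was called in 18 of 20 runs, with 0 of 19 unchanged lists called on average. The simulated genes varied independently, the lists were drawn at random, and no difference between replicate numbers was included. In the data the estimated inter-gene correlation was 0.61 for histones and 0.93 for G1/S genes. The runs therefore do not show how often lists of correlated genes are called falsely.

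The alternatives were no filter and a 50th percentile filter, repeated quantile normalisation, median centring, cyclic loess, a trended and a robust prior, the mean of a gene's probe sets, all probe sets, a block for replicate number, fold limits of 1.5 and 2, other list tests, and leaving out each array. Replicate numbers 1 and 2 appear in both lines, but the labels do not say that a number marks a shared culture, day or batch, so the arrays were not treated as pairs. No array date or batch was used here. The hairpin sequences were not used here, and off-target effects of the hairpin were not tested.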

Results

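DBC1 (CCAR2) is a nuclear protein known as an inhibitor of the deacetylase SIRT1 and as a partner of several transcription factors. The arrays addressed how gene expression in MDA-MB-231 cells differs when it is depleted. Expression was compared between 2 shNS control arrays and 2 shDBC1 arrays, as log2 intensities normalised by the authors. Pearson correlations between arrays, computed across probe sets, which are not independent replicates, were 0.992 for the shNS pair and 0.991 for the shDBC1 pair. The correlations across the lines were 0.995 for the arrays numbered 1, 0.993 for those numbered 2, and 0.991 for both other pairs. The closest pairs of arrays were thus pairs from different lines. Between 624 and 1465 of the 33297 probe sets had identical values in any pair of arrays, so no array was a copy of another.

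CCAR2, the hairpin's target, was 2.08-fold lower in shDBC1 cells. Its probe set (8145201) had a log2 intensity of 9.51 ± 0.14 in shNS and 8.46 ± 0.43 in shDBC1 (SD, n = 2), a difference of -1.06 (SE 0.23, interval -1.67 to -0.44). This corresponded to 48.1% of the control intensity. The single arrays read 9.62 and 9.41 in shNS against 8.76 and 8.16 in shDBC1, so both knockdown arrays lay below both controls. The limma adjusted p was 1 over all genes in the fit by group alone, and the difference did not pass the threshold. With a replicate block, given with the alternatives, it passed (limma adjusted p 0.0232). The labels do not say what a replicate number shares. SIRT1 itself differed by -0.01 (SE 0.13, interval -0.35 to 0.32), a value that was 0.0015 after repeated quantile normalisation.

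The genes with the smallest p, CXCL10 and CTNS, had lower intensities in shDBC1 cells, and neither passed the threshold in the fit by group alone. Both passed with a replicate block (limma adjusted p 0.00193 and 0.00575). CXCL10, an interferon-inducible chemokine, was 4.90-fold lower, at 8.28 ± 0.013 in shNS and 5.99 ± 0.26 in shDBC1 (SD, n = 2; interval of the log2 difference -2.71 to -1.87). Both its shDBC1 readings lay below the filter level of 6.58, and how far they stood above background was not analysed here, so the size of this fold is uncertain. CTNS, the lysosomal cystine transporter, was 2.52-fold lower, with a log2 difference of -1.33 (SE 0.10). MMP1, interstitial collagenase, was 2.36-fold lower, at 11.2 ± 0.23 against 9.98 ± 0.041 (interval of the difference -1.63 to -0.84). PDE7B, a cAMP phosphodiesterase, was 2.72-fold lower (-1.44, SE 0.15), and the beta-secretase gene BACE1 was 1.85-fold lower (-0.89, SE 0.11). The neuropilin gene NRP2 differed by -0.96 (SE 0.14), the monocyte chemoattractant gene CCL2 by -0.83 (SE 0.12) and the homeobox gene IRX3 by -0.71 (SE 0.10). The remaining lower genes named by the rule were TMEM184C (-0.92), SYT15 (-0.82), PIGS (-0.78) and REEP4 (-0.73).

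In the other direction, IL24, a cytokine of the IL-10 family, was 3.19-fold higher in shDBC1 cells, at 7.94 ± 0.042 in shNS and 9.62 ± 0.31 in shDBC1 (SD, n = 2; interval of the log2 difference 1.20 to 2.15). CD22, a sialic acid-binding lectin best known from B cells, was 2.66-fold higher (1.41, SE 0.15). ANGPTL4, a secreted inhibitor of lipoprotein lipase, was 1.95-fold higher (0.96, SE 0.21). Smaller differences were measured for EXPH5 (0.86, SE 0.20), the receptor kinase gene MUSK (0.73, SE 0.12, with shNS readings below the filter level), the endothelial protein C receptor gene PROCR (0.61, SE 0.15) and DICER1, which encodes the microRNA-processing nuclease (0.57, SE 0.12). SMYD3, ACY1, PTBP2, CERS6 and CPM (carboxypeptidase M) were higher by 0.49, 0.47, 0.45, 0.44 and 0.43.

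Across the 13813 genes tested, limma called 0 genes at an adjusted p under 0.05. The smallest adjusted p was 0.589, for CXCL10 and CTNS, and each other gene named here had an adjusted p of 1. At an unadjusted p under 0.05 there were 475 genes, against 691 by chance if all arrays varied independently, and 355 of them (74.7%) were lower in shDBC1. By size, 190 genes were at least 1.5-fold lower and 52 at least 1.5-fold higher, and 23 were at least 2-fold lower and 5 at least 2-fold higher. Both shDBC1 arrays lay outside the range of the shNS arrays on one side for 3433 genes (24.9%), against 33.3% by chance for 2 independent arrays against 2. Same-numbered arrays deviated together from their group means (correlation 0.653 across genes). The fit by group alone left that shared part in its error, so these counts can fall below the chance values. A fit with a replicate block is given with the alternatives. The count of 475 became 203 without the second shNS array, with 57.6% lower, and 202 without the second shDBC1 array. The median SE was 0.135 on the log2 scale, and the intervals reached a median of 0.356 to either side of the estimate.

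**Figure D1:**
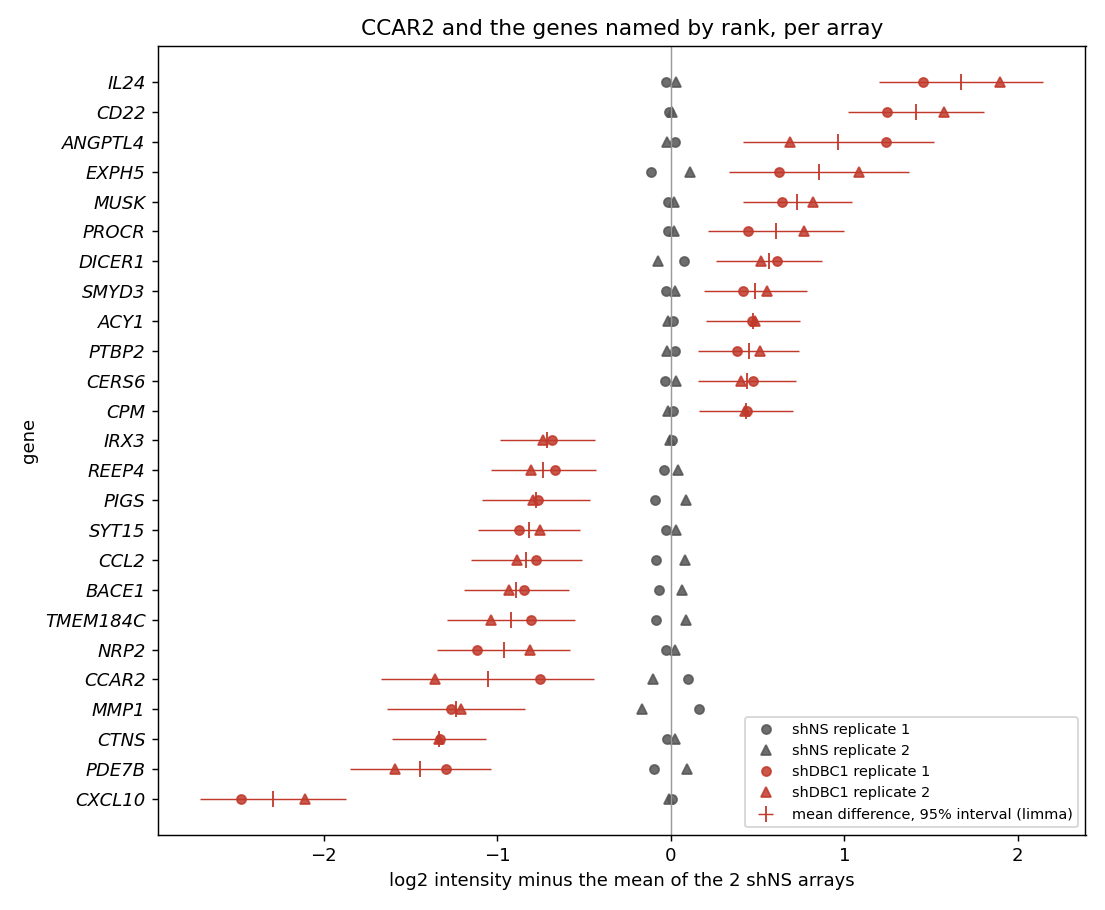
Log2 intensity of CCAR2 and the 24 genes named by rank on each of the 4 arrays, minus the mean of the 2 shNS arrays of that gene, with ticks and bars for the mean difference and its 95% interval in limma. CXCL10 differs by -2.29, with shDBC1 readings below the filter level of 6.58. In each gene both shDBC1 arrays lie on the same side of both shNS arrays, as the rule required of the 24. None passed the limma threshold in the fit by group alone, which is the fit shown.

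Among the 22 gene lists, of which 4 were called, replication-dependent histones showed the lowest values relative to other genes, and genes of the G2 and M phases of the cell cycle were also shifted lower. Camera gave an adjusted p of 8.32e-07 for histones and 3.65e-05 for G2/M genes at the preset correlation, and both calls were lost in fry (0.926) and with an estimated correlation (adjusted p = 0.677 with an estimated correlation). The latter test had only 2 degrees of freedom, so this loss does not decide whether correlation among members made the calls. All 16 tested histone genes had a negative fold change, 11 of them with both shDBC1 arrays below both shNS arrays, and the median was -0.26. H2BC12 differed by -0.71 (SE 0.26), H3C10 by -0.44 (SE 0.18) and H3C2 by -0.38 (SE 0.14). The list's median difference from the shNS mean was -0.12 on the first shDBC1 array and -0.37 on the second. Of 31 G2/M genes 30 were below zero, 9 with both arrays below, and the median was -0.14. The mitotic kinase gene AURKA differed by -0.50 (SE 0.16), HMMR by -0.55 (SE 0.22) and the survivin gene BIRC5 by -0.31 (SE 0.17). The G1/S and replication list was not called (camera adjusted p = 0.203), with 10 of 30 members below zero, MCM6 at 0.31, CCNE1 at 0.33, and list medians of 0.30 on the first and -0.13 on the second shDBC1 array. None of the members of either list passed adjusted over the list alone. Without the first shNS array the G2/M adjusted p was 0.10 and 14 of the 22 lists were called, and without the second shDBC1 array 17 were called. The G1/S list was called higher without the second shDBC1 array or the first shNS array, and lower without the first shDBC1 array. Leaving out 1 array leaves part of the difference between arrays numbered 1 and 2 in the comparison. All 30 G1/S genes were lower in the arrays numbered 2 in both lines, so these calls cannot be told apart from that difference. These calls rest on the preset correlation, and over all 4 arrays the G1/S list had an adjusted p = 0.859 with an estimated correlation.

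Inflammatory and interferon-responsive genes were the other lists shifted lower at the preset correlation, with a camera adjusted p of 0.00836 for the NF-kB list and 0.00932 for the interferon list. Both calls were lost in fry (0.926) and with an estimated correlation (adjusted p = 0.677 with an estimated correlation). For the NF-kB list the estimated correlation was -0.0048, below the preset 0.01. Its unadjusted camera p still went from 0.00114 to 0.0680, so that loss came with the few degrees of freedom. For the interferon list the estimated correlation was 0.092, above the preset, so the correlation and the degrees of freedom both entered its loss. Of 26 tested genes of the NF-kB and inflammatory cytokine list, 20 had a negative fold change, 10 with both arrays below and 4 with both above, and the median was -0.17. The neutrophil chemokine genes CXCL1 and CXCL8 differed by -0.89 (SE 0.21) and -0.60 (SE 0.22), CCL2 by -0.83 and the inhibitor gene NFKBIA by -0.50 (SE 0.17). IL24 went the opposite way within this list (1.67, SE 0.18). Adjusted over the list alone, IL24 (adjusted p = 0.00949) and CCL2 (adjusted p = 0.0177) passed in limma. Of 29 interferon response genes, 20 were below zero, 9 with both arrays below and 0 with both above, and the median was -0.11. IRF1, a transcription factor of the pathway, differed by -0.49 (SE 0.18), XAF1 by -0.41 (SE 0.17), RSAD2 by -0.33 (SE 0.14) and SAMD9 by -0.28 (SE 0.11). None passed adjusted over the list alone, and the list's median difference from the shNS mean was -0.24 on the first shDBC1 array and 0.026 on the second. The list's mean level was 8.64 on the first and 8.79 on the second shNS array. It was 8.49 on the first and 8.71 on the second shDBC1 array, each below the same-numbered shNS array. The camera adjusted p values of the NF-kB and interferon lists were 0.273 and 0.272 without the second shNS array, and 0.0936 and 0.803 without the first shDBC1 array.

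The PEA3 subfamily of ETS transcription factors, reported to act with DBC1, had small differences in its own transcripts, with intervals that included 0. ETV1 differed by -0.03 (interval -0.55 to 0.49), ETV4 by -0.26 (-0.66 to 0.13) and ETV5 by -0.12 (-0.41 to 0.17). For ETV1 the value was 0.22 without the second shNS array and 0.0048 without the first shDBC1 array. In the list of these factors and their reported targets, 15 of 20 tested members were below zero, with 7 below and 4 above on both arrays and a median of -0.074. The camera adjusted p was 0.0518, which was 0.0127 with no intensity filter, 0.0143 without the first shNS array, 0.0196 without the second shDBC1 array and 0.667 without the second shNS array (0.677 with an estimated correlation). MMP1 was the only member to pass adjusted over the list alone (adjusted p = 0.0128 in limma). CXCR4, a chemokine receptor, differed by -0.65 (SE 0.14). MMP3, MMP7, MMP10, MMP13 and SPP1 were too dim to be tested. The protease and inhibitor list gave a camera adjusted p of 0.146 over 23 members, and was called lower with no filter (0.0300). It pointed higher without the first shDBC1 array or the second shNS array. In this list TIMP3 was at -0.72 (SE 0.25), ADAMTS6 at 0.69 (SE 0.26) and ADAM12 at -0.24. MMP1 passed adjusted over the list alone (adjusted p = 0.0147 in limma).

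Adhesion and differentiation genes contained single large differences, and none of their lists was called at the main settings. The epithelial list was called lower with a replicate block (camera adjusted p = 0.0394). Without the first shDBC1 array, which unbalances the replicate numbers, the integrin, mesenchymal and epithelial lists each pointed higher. The collagen-binding integrin gene ITGA2 was 1.97-fold lower (-0.98, SE 0.22) and the tetraspanin gene CD82 differed by -0.40 (SE 0.13), while the integrin and adhesion list had 9 of 19 members below zero (camera adjusted p = 0.725). Its median of 0.0063 and its mean of -0.020 differed in sign, and the test pointed lower. CDH11 (-0.88, SE 0.24) and S100A4 (-0.64, SE 0.11) were lower and TAGLN higher (0.33, SE 0.12) among 28 mesenchymal genes, of which 14 were below zero. That list had a camera adjusted p of 0.332, with a median of 0.0015 against a mean of -0.065 and a test pointing lower. Of 24 epithelial junction and keratin genes 14 were below zero (camera adjusted p = 0.147), with CLDN1 at -0.73 (SE 0.18) and KRT80 at -0.43 (SE 0.14).

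The signalling lists were not called over all 4 arrays at the main settings. Under the 50th percentile filter p53 targets were called higher (camera adjusted p = 0.0255). With 1 array left out, the Wnt list was called lower without the second shNS array and the immediate early list lower without the first shNS array. TGF-beta targets were called lower without the first shNS or the second shDBC1 array, and p53 targets higher without the second shDBC1 array. Such fits rest on the preset correlation and unbalance the replicate numbers. Over all 4 arrays none of the 22 lists had an adjusted p below 0.677 with an estimated correlation. ID1 and ID3, which encode inhibitors of helix-loop-helix factors, differed by -0.92 (SE 0.31) and -0.91 (SE 0.26) in the TGF-beta list, where 14 of 25 members were below zero (camera adjusted p = 0.480). BMP4 (-0.59, SE 0.12) and FZD7 (-0.51, SE 0.11) were the lower members with the smallest p of the Wnt list, which had 10 of 20 members below zero (0.147). MYC was higher by 0.34 (SE 0.15). YAP/TAZ targets had 5 of 20 members below zero (0.146), with CCN1 at 0.37 and CCN2 at 0.27, and IGFBP3 at -0.49. The immediate early and MAPK feedback list had 21 of 32 below zero (0.146), with SPRY4 at -0.49 and DUSP1 at 0.59. In the p53 target list 8 of 23 were below zero (0.162), with GADD45A at 0.51, PMAIP1 at 0.39 and TP53INP1 at -0.45.

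Metabolic and stress lists were likewise not called at the main settings. Each list in this paragraph turned direction in at least 1 fit with an array left out, which unbalances the replicate numbers. The sterol synthesis enzyme gene MSMO1 was 2.19-fold lower (-1.13, SE 0.31), with 12 of 19 cholesterol genes below zero (camera adjusted p = 0.297). AKR1C1 and AKR1C2, close copies that encode aldo-keto reductases, differed by -0.88 (SE 0.29) and -0.75 (SE 0.15), with 13 of 22 NRF2 targets below zero (0.249). SLC7A11, the cystine importer gene, differed by -0.53 (SE 0.19) in the unfolded protein and amino acid stress list, where 24 of 30 were below zero (0.0722, and 0.0200 on ranks, against adjusted p = 0.794 with an estimated correlation). EGLN3 (-0.73, SE 0.33) and TPI1 (-0.34, SE 0.12) were lower and ANGPTL4 higher in the hypoxia and glycolysis list, with 22 of 31 below zero (0.332). HSPB8 was higher by 0.77 (SE 0.27) among heat shock genes, of which 6 of 15 were below zero (0.376). PER3 differed by -0.34 (SE 0.13) in the clock list, with 11 of 16 below zero (0.236). Among DBC1 partners, CCAR2 itself aside, HDAC3 at -0.18 and PARP1 at 0.17 had the smallest p (13 of 20 below zero, 0.223).

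Markers of other cell types gave counts only, and 0 members of any of the 6 lists passed. Negative fold changes were found in 8 of 12 luminal epithelial, 4 of 7 basal, 4 of 7 leukocyte, 2 of 6 endothelial, 1 of 5 fibroblast and 1 of 2 embryonic kidney or neural-like markers tested. The luminal markers had a median of -0.25, near the -0.26 of the histone list, with medians of -0.35 on the first and -0.010 on the second shDBC1 array, and no list test was made of them.

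**Figure D2:**
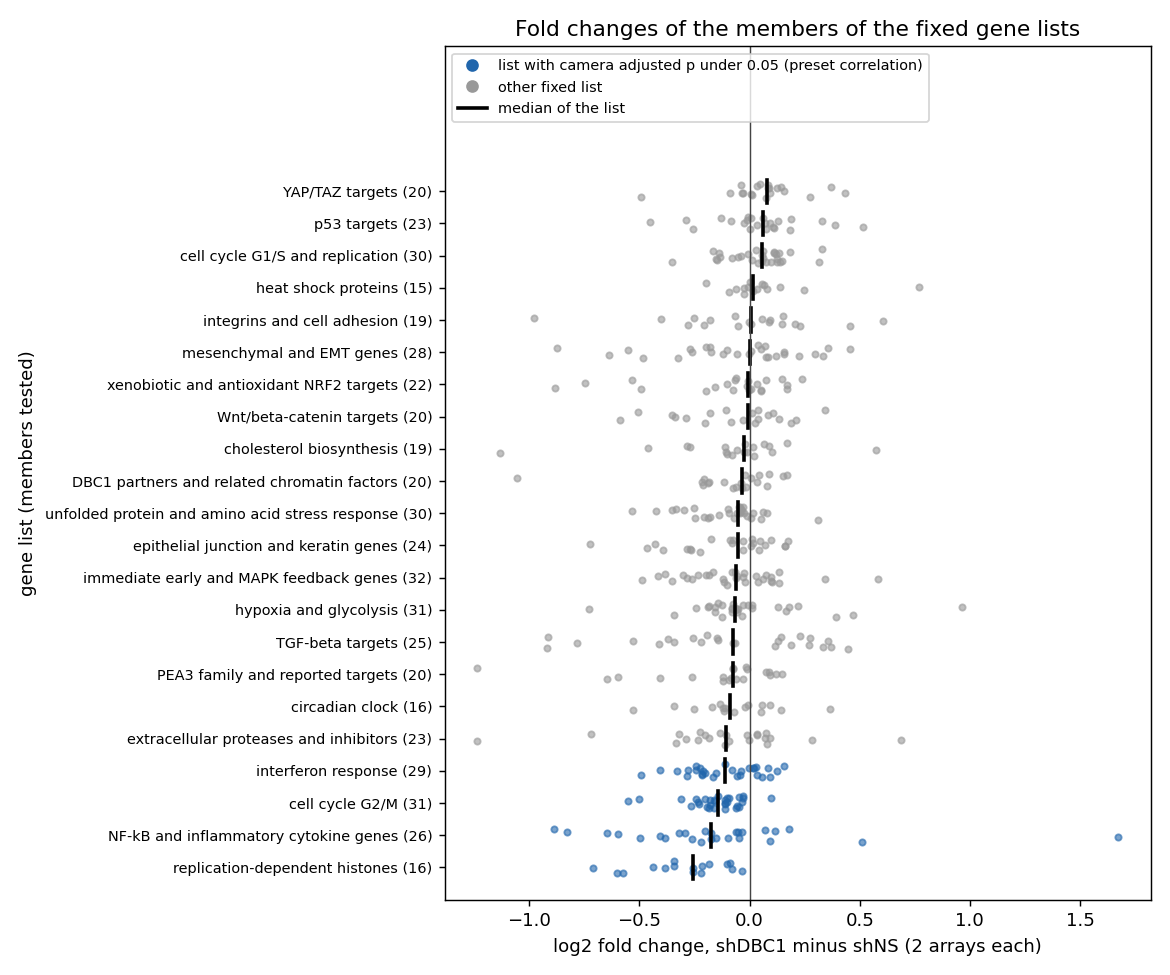
Log2 fold changes (shDBC1 minus shNS, 2 arrays each) of the tested members of the 22 gene lists, 1 point per gene, with the list median as a black bar and the number of members tested in brackets. The 4 lists in blue, with medians from -0.26 to -0.11, had a camera adjusted p under 0.05 at the preset correlation, and none did with an estimated one. The latter test had only 2 degrees of freedom, and the estimated correlation ran from -0.0048 for the NF-kB list to 0.61 for histones.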

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

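All alternatives here were planned. The count of 0 genes past the limma threshold was the same under each filter, scaling, prior and left-out array, and over all probe sets. With a replicate block it was 113 genes (19 higher, 94 lower), of which 84 were among the 475 at an unadjusted p under 0.05 without the block. The deviations of same-numbered arrays from their group means correlated at 0.653 across genes, but with only 2 numbers and no label for what they share this is a hint from the data, and the arrays were not treated as pairs. Under the block CCAR2 stayed at -1.06 and passed (adjusted p 0.0232), 27 of the 106 other named genes passed, the genes at an unadjusted p under 0.05 were 1612, and 7 lists were called in place of 4. A fold of at least 2 with no test gave 28 genes. All probe sets together gave 1123 at an unadjusted p under 0.05, with more features tested. Leaving out 1 array gave 202 to 553 such genes, with 57.6% to 74.1% of them lower, and put CCAR2 between -1.36 and -0.75. It leaves 1 line with a single array, assumed to vary like the other line, and by construction unbalances the replicate numbers between the lines. The lists called then numbered 3 to 17, against 6 with no filter, 6 with the mean of probe sets, 5 on ranks and 0 with an estimated correlation or in fry. There the histone, G2/M, NF-kB and interferon lists each had adjusted p 0.677 and 0.926. Calls were gained, all lower except p53 targets, by the PEA3 list with no filter (0.0127), the mean of probe sets (0.0455) and the block (0.0299), by unfolded protein genes on ranks (0.0200), with the mean of probe sets (0.0455) and the block (0.0254), by proteases with no filter (0.0300), by epithelial genes with the block (0.0394) and by p53 targets under the 50th percentile filter (0.0255). The NF-kB call was also lost under the 50th percentile filter (0.0996), which tests fewer members. Without 1 array the adjusted p ran from 0.00649 to 0.273 for NF-kB, 1.3e-05 to 0.803 for interferon and 8.77e-07 to 0.10 for G2/M genes, and histones kept their call (1.63e-09 to 0.00924). The direction turned in at least 1 alternative for 13 of 22 lists, none of them among the 4 called, and apart from the integrin list only when an array was left out. The adjusted p ranges over the left-out arrays were 0.00306 to 0.803 for proteases, 0.0147 to 0.993 for mesenchymal, 0.000206 to 0.931 for epithelial, 0.0196 to 0.289 for integrin, 0.00504 to 0.931 for clock, 6.63e-09 to 0.524 for G1/S (called higher at 6.63e-09 and 0.0143 and lower at 0.0117), 0.00282 to 0.289 for hypoxia, 0.00282 to 0.733 for unfolded protein, 0.0487 to 0.931 for heat shock, 0.041 to 0.736 for cholesterol, 0.0101 to 0.527 for TGF-beta, 0.057 to 0.808 for DBC1 partner and 0.000206 to 0.736 for NRF2 genes. For lists that kept their direction they were 0.0143 to 0.667 for PEA3, 0.0267 to 0.893 for Wnt, 0.0297 to 0.691 for immediate early, 0.0487 to 0.518 for p53 and 0.0936 to 0.452 for YAP/TAZ genes. These values are at the preset correlation. The integrin list also turned with the block (0.803) and on ranks (0.853). Of the 106 other named genes 4 turned direction. SIRT1 was 0.0015 after repeated quantile normalisation and -0.12 to 0.093 without 1 array, where ETV1 ran from -0.28 to 0.22, MCM2 from -0.014 to 0.38 and DNAJB4 from -0.087 to 0.58. Beyond the fewer arrays or features named, and the unbalanced replicate numbers when an array was left out, the cause was not tested. Under the 50th percentile filter 88 of the 106 genes had a value, and camera takes no robust prior, so no list value was made for it. How far dim genes stand above background was not analysed here, and 4604 were left out as dim.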

Other observations

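The comparison of arrays by replicate number, and the tests of small RNA yield and of growth state, were chosen only after the result was seen. Replicate number is not a comparison of the design. With the cell line as a block, limma found 1565 genes that differed between the arrays numbered 2 and those numbered 1 (adjusted p under 0.05), 1122 higher and 443 lower in those numbered 2. TCP11L2 was higher by 2.07 (SE 0.12) on the log2 scale, the carboxypeptidase gene CPE by 1.65, the chromatin organiser gene SATB1 by 1.60, the fatty acid desaturase gene SCD by 1.47, the prostaglandin synthase gene PTGS2 by 1.28, the E-cadherin gene CDH1 by 1.19 and the cell cycle inhibitor gene HBP1 by 1.25. Lower genes included RRS1 (-1.16), CTPS1 (-1.10), NOP2 (-0.74), RRP12 (-0.74), ODC1 (-0.70) and CAD (-0.68). These genes were chosen after their values were seen, and no list or enrichment test stands behind them. Among the gene lists, all 30 G1/S and replication genes were lower in both lines, with median differences of -0.28 in shNS and -0.39 in shDBC1 (camera adjusted p 2.02e-11). Hypoxia and glycolysis genes (3.68e-06) and TGF-beta targets (4.79e-06) were shifted higher, and further lists were called. Lists called for shDBC1 were among them: G2/M genes (0.00103) and histones (0.0134) were lower and interferon genes (0.0104) higher. The NF-kB list was not called (0.121). Each list call by replicate number was lost with an estimated correlation, where no list had a camera adjusted p below 0.557.

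CXCL11 and GBP4, chosen after their values were seen, are interferon-inducible genes outside the lists. Like CXCL10 they were lower in shDBC1 cells without passing the threshold, CXCL11 by a log2 difference of -1.52 (SE 0.27, with a shDBC1 mean of 5.98 that lies below the filter level) and GBP4 by -1.06 (SE 0.24). The luminal markers MUC1 (-1.16, SE 0.30) and GATA3 (-0.47, SE 0.12), chosen the same way, were also lower. Of the 12 luminal markers tested, 4 were above zero and 2 had both shDBC1 arrays below both shNS arrays.

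The arrays differed between replicate numbers within both lines. Scaling between arrays was argued against, since cyclic loess gave 2084 genes, 133% of the 1565. A difference in the yield of small RNAs stays open for those genes: 32 of the 1565, 2.04%, were small RNA genes, 31 of them lower in the arrays numbered 2, but with only 184 small RNA genes tested this share could not have been large and decides nothing. A different growth state of the cultures may be a candidate explanation and stays open: 100% of the G1/S members were lower in both lines, but that is the observation that prompted it, over members that vary together, and not an independent test. The design names no biological difference between replicate numbers, so no biological explanation from it was tested.

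In shDBC1 cells 20 of 29 interferon and 20 of 26 NF-kB list members had negative fold changes, with a pooled median of -0.15 over 55 genes. None passed the threshold over all genes in the fit by group alone. Removing the difference between replicate numbers left 82.3% of that median, which decides nothing, since each line holds 1 array of each number and a difference shared by the lines cancels by construction. Scaling that differs with intensity was argued against, since the pooled median relative to all genes was -0.164 after repeated quantile normalisation and -0.170 after cyclic loess. A shift shared by all genes cancels in this relative median by construction, so it was not tested. The NF-kB and interferon calls were lost with an estimated correlation (camera adjusted p = 0.677) and in fry (0.926). They were also lost without the second shNS array or the first shDBC1 array. Leaving out either array unbalances the replicate numbers. By number the interferon list was itself higher in the arrays numbered 2 (camera adjusted p 0.0104), and the NF-kB list was not called (0.121). These losses therefore cannot tell a single array from that difference, and dependence on single arrays stays open. Lower inflammatory and interferon-responsive transcription after DBC1 depletion may be followed up as a hypothesis, found and tested on the same data with 1 line per group. Whether it holds for other lines or hairpins was not tested.

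Of the 475 genes at an unadjusted p under 0.05, 74.7% were lower in shDBC1 cells. Scaling was argued against, since the share was 72.2% after repeated quantile normalisation and 77.1% after cyclic loess. An effect of 1 intensity class stays open, since the share was 63.3% among the dimmest genes, 74.0% in the middle and 81.0% among the brightest. The share was 57.6% without the second shNS array, but leaving out an array unbalances the replicate numbers. By number, 1122 genes were higher and 443 lower in the arrays numbered 2 (limma adjusted p under 0.05). That fit therefore cannot tell a single array from this difference, and dependence on a single array stays open. With a replicate block, which leaves out no array, the share was 65.1% of 1612 genes. Depletion of DBC1, the difference that the design names, stays open as untested beside these.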
